A study of Mus musculus with 3 samples.

How the data were processed

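Total RNA of 3 samples of cultured mouse dorsal root ganglion neurons, 1 per condition, was labelled with Cy3 and hybridised to Arraystar mouse arrays that are read in 1 colour, per the labels. All 3 arrays lay on 1 slide and were read in 1 scan, per the file headers, so no slide or scan contrast exists between the conditions, while the position on the slide (1, 2 and 3) goes with the condition. The deposited scanner files hold an intensity per spot, background-subtracted and detrended, with low values replaced, by Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes and the file headers. The header of the vehicle array shows no multiplicative detrending fit (0), while those of the melatonin and 8-M-PDOT arrays show one (root mean square 0.046 and 0.044). The files also hold other columns, which are the deposited flags for spots well above background, saturated or outlying. A value table in log2 units was deposited by the authors, and its normalization is not given in the sources used here. Over its brighter probes, its values differed from quantile-normalized log2 processed signals by a median absolute difference of at most 0.000332 per array. Dim probes were left out of that figure. The column medians of the whole table were 6.27 for each array, and its lowest value was 2.32. The series design names a random variance model and a paired t-test, which 1 array per condition does not allow, and neither was run.

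From these files the log2 processed signal of each spot was averaged over the spots of a probe, and the 75th percentile of the array over study probes was subtracted. Control spots, 15 negative-control probes and spots with an outlier flag on any array were left out, which removed 69 further probes and left 60846. The 15 genes below kept 14 to 20 of their 20 spots, so the SD over spots leaves out outlying spots. A probe counted as measured in a comparison when it was well above background on at least 1 of the arrays compared, and a dim value was raised to the lowest signal among probes well above background on its array (19.3, 15.7 and 14.4 units). Ratios against a raised value are lower bounds. Probes were counted past a threshold of 2-fold (log2 ratio of 1). No p-value or standard error was computed because each condition has 1 array, and the number of arrays limits the precision.

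The SD between replicate spots had a median of 0.06 (log2) for probe means above 8 log2 units and 0.31 below 5. The counting step was tested on simulated data for melatonin against vehicle, over 46504 probes with 50 probes changed at each size. The changed probes were drawn from those well above background on all 3 arrays, so recovery of changes in dim probes was not tested. The counting step recovered 98% of changes of 1.5 log2 units and 100% of changes of 2, 3 and 4, and called 347 of 46304 unchanged probes. Its noise was the SD between spots of an array, so this number leaves out any spread between cultures, labellings and arrays and is no rate of false calls between conditions. The simulation of unchanged arrays for the shared vehicle took its noise from the difference of the treated arrays instead, which includes real differences. It gave all 3 arrays the same noise. Percentiles of lists come from 10000 random lists of the same size matched on mean expression in 20 bins and describe these arrays. Lists hold probes well above background on at least 1 of the 3 arrays, so members dim on both arrays compared enter at or near the floors.

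The rule for named genes, fixed before the data were examined, took the coding genes with the highest and lowest ratios that passed 2-fold in the main setting and after background modelling, up to 4 members of each gene list, and the melatonin receptor genes. The files pair only 15 of the study probes with a RefSeq accession. All 15 accessions matched a gene in the reference table (assembly GRCm38.p6), while the array grid names the mm9 build, so no coordinates are given. The ranking of coding genes, the split into coding and non-coding probes, the choice of a probe per gene, the melatonin receptor genes and the cell type markers (0 of them named) were therefore not analysed here. Of 26 gene lists, 24 had no member named by accession, glycolysis had 1 (Gapdh), and the housekeeping list had 7. Pgk1 is on the glycolysis and housekeeping lists, but only control probes carry its name, so it was left out of both. B2m, Hprt, Tbp, Actb and Gapdh follow from the rule for gene lists. The other 10 named genes are given because no other study probe is paired with a gene, a choice made after the values were seen. For the ranking, 1 probe identifier in each direction is given per comparison against vehicle. Counts are per probe, not per gene, and the genes G6pd2 and Ldhal6b are uncertain because they are near-copies of other genes.

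Alternatives were normexp background modelling (limma 3.58.1 in R 4.3.3, offset 50) on the median spot and local background signals with quantile normalization or with the 75th percentile, quantile normalization, median scaling, the 75th percentile over the 41238 probes well above background on all 3 arrays, the deposited value table, no filter on dim probes, only probes well above background on all arrays, and thresholds of 1.5-fold and 4-fold. The plan named the mean spot signal for normexp, and the median stood in for it because the files have no mean column. The main setting and the first 6 of these are the 7 scalings. They are not 7 separate checks. Median scaling and the 75th percentile over probes well above background on all 3 arrays shift every ratio of the main setting by a constant. The deposited value table is close to quantile normalization. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.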

Results

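Primary dorsal root ganglion neurons, the cell bodies of the sensory nerves that carry pain and touch signals, were cultured from C57BL/6 mice aged 5 to 9 days. After 5 days in culture they were incubated for 24 h with vehicle (1% ethanol in saline), with 1 mM melatonin, or with 100 µM 8-M-PDOT, an agonist of the melatonin receptor 1B. The sample labels name ethanol for the vehicle alone and give no solvent for the treated cultures. RNA from each of the 3 conditions was hybridised to 1 single-colour array that carries probes for long non-coding and protein-coding transcripts. Each condition therefore had 1 array, and the differences below describe 3 arrays with no replicate check and no test between conditions. The SD given with a gene is the spread of its replicate spots within the arrays, which is technical. The vehicle, melatonin and 8-M-PDOT arrays had 44580, 45094 and 45007 of 60846 probes well above background. Their 75th percentile signals were 477, 454 and 328 intensity units, and no probe was saturated. The files pair 15 probes with a RefSeq accession and therefore with a gene, and the named results rest on those 15 genes.

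The comparison of melatonin with vehicle addressed which transcripts differed at least 2-fold after melatonin, the threshold named in the series design. B2m, which encodes the light chain of major histocompatibility complex class I, stood furthest from vehicle among the named genes. Its signal was 5.93-fold higher on the melatonin array (log2 ratio 2.57 ± 0.05, SD of the ratio over 19 spots). Gusb, the lysosomal enzyme beta-glucuronidase, was 2.53-fold higher (1.34 ± 0.06, 17 spots). Tfrc, the transferrin receptor that takes up iron, was 2.26-fold lower (-1.18 ± 0.05, 19 spots). These were the only 3 of the 15 named genes past 2-fold. All 3 stayed past it in each of the 7 ways of scaling the arrays, which are not independent checks. G6pd2, a retrogene copy of glucose-6-phosphate dehydrogenase uncertain because its sequence is close to that of its parent gene, had a log2 ratio of 0.94 ± 0.10, and 1 of the 7 scalings put it past 2-fold. Cytoskeletal Actb was at 0.58 ± 0.07 and the purine salvage gene Hprt at -0.67 ± 0.08.

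The other named housekeeping genes differed less between the melatonin and vehicle arrays. Gapdh of glycolysis, Ppia (cyclophilin A) and Tuba1b (alpha-tubulin) had log2 ratios of -0.22, -0.25 and -0.24. The ribosomal protein gene Rpl13a and the TATA-binding protein gene Tbp had log2 ratios of 0.09 and 0.12. The signs of Hsp90ab1, a chaperone gene (-0.11), and Nono, a nuclear RNA-binding protein gene (-0.01), depended on the scaling, with ranges of -0.15 to 0.13 and -0.05 to 0.24. Among 2000 probes closest in mean brightness, 0.3% were as high on the melatonin array relative to vehicle as B2m, 5.05% as high as Gusb, and 2.5% as low as Tfrc.

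Across all probes, 2833 of 46504 measured probes (6.09%) were at least 2-fold higher on the melatonin array and 2390 (5.14%) at least 2-fold lower. Differences of at least 8-fold were rarer, with 116 probes higher and 74 lower. The probe with the highest ratio among those well above background on both arrays was ASMM10P002419, at a log2 ratio of 7.95. It was also higher on the 8-M-PDOT array, at 7.19. The probe with the lowest ratio, ASMM10P036258, was at -5.37 with melatonin and at -2.83 with 8-M-PDOT. The files do not pair these probes with a gene. With background modelling in place of the processed signal, the counts were 1371 higher and 1370 lower.

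The comparison of 8-M-PDOT with vehicle asked the same of the receptor agonist. B2m was again the furthest above vehicle among the named genes, 7.28-fold higher (log2 ratio 2.86 ± 0.05, 19 spots). Actb was 3.99-fold higher (2.00 ± 0.06, 19 spots) and Rpl13a 2.24-fold higher (1.16 ± 0.03, 20 spots). Hprt was 4.63-fold lower (-2.21 ± 0.08, 20 spots) and Tbp, part of the machinery that starts transcription, 4.53-fold lower (-2.18 ± 0.08, 18 spots). These 5 genes were past 2-fold in all 7 scalings, some of which only shift every ratio by a constant. Nono (-0.91 ± 0.06) was past 2-fold in 1 scaling and the lactate dehydrogenase-like retrogene Ldhal6b (-0.90 ± 0.23), a dim probe, in 3. Gusb had a log2 ratio of 0.66 ± 0.08 and Gk, glycerol kinase, of 0.34 ± 0.15. Tfrc was at 0.25 ± 0.10 and G6pd2 at -0.14 ± 0.08.

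Among the abundant housekeeping genes, Gapdh, Tuba1b, Ppia and Hsp90ab1 had log2 ratios of -0.05, -0.02, 0.07 and 0.02 on the 8-M-PDOT array relative to vehicle. The sign of each depended on the scaling, over ranges of -0.45 to 0.07, -0.42 to 0.10, -0.33 to 0.20 and -0.13 to 0.14. Of 2000 probes of like brightness, 0.9% were as high as B2m, 3.1% as high as Actb, 2.45% as low as Hprt and 6.6% as low as Tbp.

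**Figure D1:**
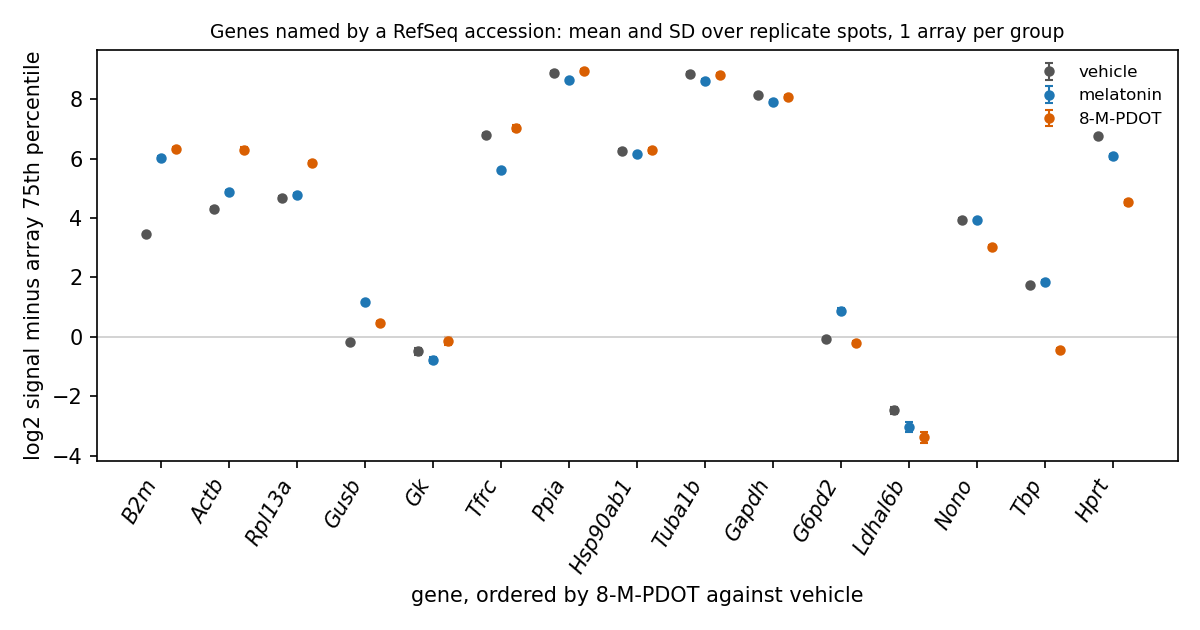
Log2 signal minus the 75th percentile of its array (y axis, log2 units) for the 15 genes named by accession (x axis), with 1 point per array and bars for the SD over 14 to 20 replicate spots. B2m lies at 3.47 on the vehicle array and at 6.03 and 6.33 on the melatonin and 8-M-PDOT arrays, and Tbp at 1.74, 1.86 and -0.44.

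The 8-M-PDOT array differed from vehicle at more probes than the melatonin array did. Of 47822 measured probes, 8171 (17.1%) were at least 2-fold higher and 7545 (15.8%) at least 2-fold lower, 3.01 times as many in all as with melatonin. The higher probes were the larger group in this scaling, while median scaling gave 7027 higher and 9118 lower. At least 8-fold differences numbered 1521 higher and 525 lower. The SD of the log2 ratio over probes was 1.37, against 0.69 for melatonin. Probe ASMM10P013598 had the highest ratio (log2 ratio 9.85) and stood at 1.77 on the melatonin array. Probe ASMM10P046152 had the lowest, -6.37, and stood at -1.82 on the melatonin array. With background modelling and quantile normalization, the counts were 5110 higher and 4892 lower.

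**Figure D2:**
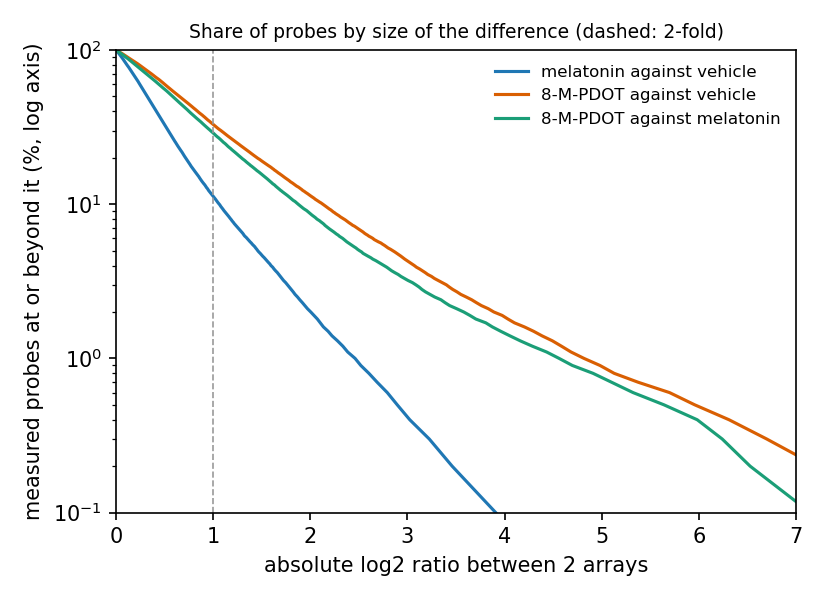
Percent of measured probes (y axis, log scale) at or beyond an absolute log2 ratio (x axis) in each of the 3 comparisons, with the 2-fold threshold as a dashed line. At 2-fold the curves stand at 11.2% for melatonin against vehicle, 32.9% for 8-M-PDOT against vehicle and 28.9% for 8-M-PDOT against melatonin.

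The compounds were also set side by side. Both have a methoxy group and an amide, on the indole of melatonin and on the tetralin of 8-M-PDOT. Their doses differed, 1 mM against 100 µM, so the values are not at a matched dose. B2m was similarly placed on both treated arrays, 0.29 ± 0.05 apart on the log2 scale. Tfrc was 2.69-fold higher on the 8-M-PDOT than on the melatonin array (1.43 ± 0.08), Actb 2.68-fold higher (1.42 ± 0.07) and Rpl13a 2.10-fold higher (1.07 ± 0.06, past 2-fold in 3 of 7 scalings). Tbp was 4.93-fold lower (-2.30 ± 0.07), Hprt 2.91-fold lower (-1.54 ± 0.06) and G6pd2 2.11-fold lower (-1.08 ± 0.06, past 2-fold in 5 of 7 scalings). Over all 47798 measured probes, 7327 were at least 2-fold higher and 6498 at least 2-fold lower on the 8-M-PDOT array. Which direction held more depended on the scaling, with 6431 higher and 7490 lower under median scaling and 4124 and 4345 under background modelling with quantile normalization.

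The housekeeping gene list fixed beforehand had 7 of its 14 members named by accession, Actb, B2m, Gapdh, Gusb, Hprt, Ppia and Tbp. Pgk1, a further member, was named only by control probes and was left out. Its control probes, given below, were lower than vehicle on both treated arrays, so the medians that follow describe the 7 without it. Against vehicle, 2 of the 7 (B2m and Gusb) were at least 2-fold higher with melatonin and none was 2-fold lower. With 8-M-PDOT, 2 (B2m and Actb) were higher and 2 (Hprt and Tbp) lower. The median log2 ratio of the 7 was 0.12 with melatonin, at percentile 95.9 of 10000 random lists of the same size and brightness, and 0.07 with 8-M-PDOT, at percentile 51.2. The sign of the 8-M-PDOT median depended on the scaling, and quantile normalization gave -0.33. Control probes for the ends of Gapdh, which bear on RNA integrity, had log2 ratios of -0.30 (name ending in 3) and -0.21 (name ending in 5) for melatonin and -0.20 and -0.29 for 8-M-PDOT. Those of Pgk1 had -0.45 and -0.66 for melatonin and -0.42 and -0.38 for 8-M-PDOT.

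Of the probes with lincRNA in their name, 965 were well above background on at least 1 of the 3 arrays. By name, 549 were humanlincRNA, 356 mouselincRNA and 60 MM9LINCRNAEXON probes, so human-named probes were the largest part. The 965 were set against 10000 random lists of the same size and brightness. With melatonin, 16 were at least 2-fold higher and 17 lower than vehicle, where random lists gave medians of 52 (39 to 66 over the central 95% of lists) and 42 (30 to 54). Only 493, 301 and 53 of the 3 families were measured in this comparison. The others were dim on both arrays and none passed 2-fold, and their share in the random lists was not compared. Among measured probes, 4.26%, 3.65% and 1.89% of the families passed 2-fold, against 11.2% of all probes without matching on brightness. With 8-M-PDOT, 179 were higher, inside the random range (144 to 189), and 59 lower, where random lists gave 100 (83 to 119). Between the compounds, 191 were higher and 23 lower on the 8-M-PDOT array, where random lists gave 158 (137 to 180) and 89 (72 to 106). Over probes well above background on both treated arrays, 55 of 392, 30 of 236 and 14 of 43 of the 3 families were higher. For all probes this was 5574 of 42303. Members dim on the array used as reference can hardly count as lower. Random lists were not matched on this, so no excess is read from the higher counts with 8-M-PDOT. The lower counts with 8-M-PDOT and both counts with melatonin lay below the random range in all 7 scalings. Background modelling with quantile normalization moved the melatonin counts to 6 and 2, against 14 (7 to 22) and 12 (6 to 19), and the 8-M-PDOT counts to 96, above the random range (56 to 87), and 19, against 45 (33 to 58). This family was set up from the probe names after the files were seen.

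Both comparisons against vehicle used the same vehicle array. Over 48681 probes their log2 ratios correlated across probes at r = 0.44, where 1000 simulated sets of 3 unchanged arrays gave a mean of 0.50 (0.49 to 0.51). The simulation gave all 3 arrays the same noise, which by itself sets the correlation near 0.50, so this contrast decides nothing. Probes are not independent replicates. The covariance was 0.40 against a simulated 0.73, a difference of -0.33 (observed minus simulated). Both compounds put 1507 probes at least 2-fold higher and 1536 at least 2-fold lower, and 169 in opposite directions. Background modelling with quantile normalization gave 656 higher and 783 lower with both. Lists drawn independently would share 476 and 370, and the simulated unchanged arrays shared 4199 and 4200. The simulation of unchanged arrays takes its noise from the difference of the treated arrays, which holds any real difference between them. Its covariance and shared counts are therefore no level of no change for judging the observed ones. Part of the overlap can come from the shared vehicle array, which cannot be split. With the melatonin array as the reference, the log2 ratios of the vehicle and 8-M-PDOT arrays had a covariance of 0.05.

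**Figure D3:**
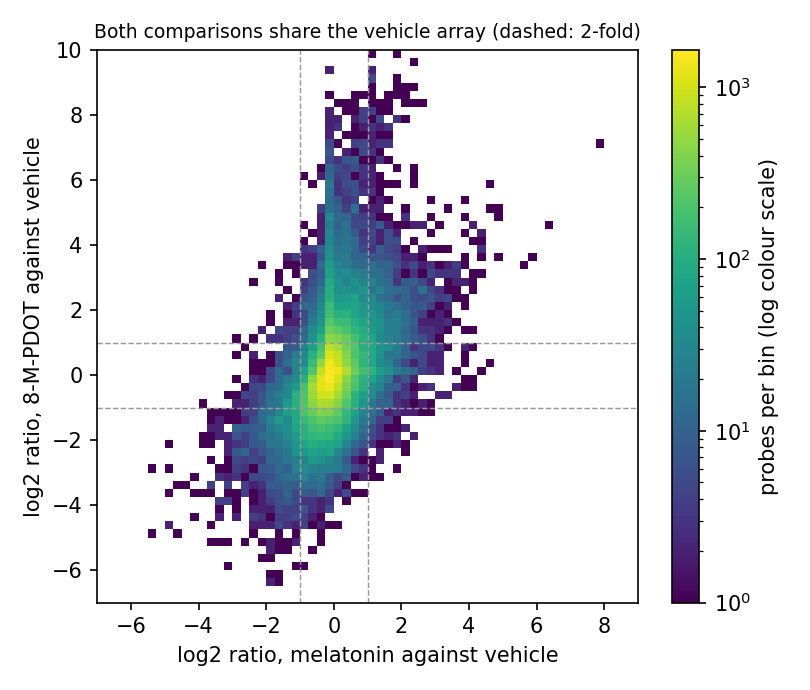
Log2 ratio of melatonin against vehicle (x axis) and of 8-M-PDOT against vehicle (y axis) for 48681 probes, coloured by the number of probes per bin on a log scale, with 2-fold thresholds dashed. Of these probes, 1507 lie at or beyond 2-fold in the upper right and 1536 in the lower left, and the 8-M-PDOT axis carries the longer tail.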

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

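All the tests of explanations in this part were chosen after the results were seen. Control probes that the comparisons leave out were set against the vehicle array, and 8 measured ratios of spike-in and external controls had a log2 value of at least 1, of which 3 rest on vehicle readings not well above background. E1A_r60_a107, a spike-in control probe with 35 spots, had a log2 ratio of 8.05 on the 8-M-PDOT array and 1.22 on the melatonin array. E1A_r60_a97 had 3.04 and E1A_r60_n11 1.11 on the 8-M-PDOT array. The external control ERCC-00062_278 was at 1.21, ETG05_36762 at 1.11 and ETG09_48764 at 4.25 on the 8-M-PDOT array, and ETG10_13482 at 2.64 on the melatonin array. On the vehicle array E1A_r60_a97, ETG09_48764 and ETG10_13482 were not well above background, and against its floor they were at least 1.66-fold, 4.66-fold and 1.64-fold higher. Control probes also stood at least 2-fold below vehicle, ERCC-00104_60 at -1.51 on the 8-M-PDOT array (28 of 35 spots well above background) and Rat-PGK1_3 at -1.07 on the melatonin array.

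A candidate explanation for the bright E1A probes is a spike-in mix added to the 8-M-PDOT sample alone. Such a mix would raise most of the 10 E1A probes, and 1 of the 10, E1A_r60_a107, was at least 4-fold higher than on the vehicle array with dim readings raised to the floor, which argues against it. A flaw of single spots would scatter the spots, and the SD over the 35 spots of E1A_r60_a107 on the 8-M-PDOT array was 0.071 (log2). What stays open is a transcript in the sample that binds these probes, and no biological explanation was tested.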

How the results depend on the processing

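The only-bright-probe counts were added after seeing the data and the others were planned. No paired analysis was possible because each condition has 1 array, and leaving out an array, fitting the slide as a block and averaging the probes of a gene were not run for the same reason or because the probes have no gene. Leaving out saturated probes changed nothing, as none was saturated. More probes differed from vehicle with 8-M-PDOT than with melatonin under each scaling and filter, from 2.49 times as many without a filter to 4.04 times with normexp and quantile normalization, and 2.08 and 5.81 times at the 1.5-fold and 4-fold thresholds. Of the 5223, 15716 and 13825 probes past 2-fold in the 3 comparisons, 2361, 9735 and 8328 stayed past it after normexp with quantile normalization. After normexp with the 75th percentile 2691, 10387 and 8511 did. In the other 6 scalings 0 passed 2-fold in the opposite direction (5220, 15644 and 13759 could be compared in the deposited table), and at most 21 changed sign. A reversal could hardly occur where a scaling only shifts every ratio by a constant, as median scaling does. Of the values that answer a comparison, 62 stayed close and 52 moved. Signal over background limits the dim probes, while 4572 of the 5223 melatonin and 13245 of the 15716 8-M-PDOT probes past 2-fold were well above background on both arrays.

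Counts that moved by over 1.5 times follow as higher and lower. For melatonin against vehicle (2833 and 2390), normexp with quantile normalization gave 1362 and 1115, normexp with the 75th percentile 1371 and 1370, and no filter 4380 and 3719. The 1.5-fold threshold gave 6000 and 6414, the 4-fold threshold 541 and 393, and bright probes 356 and 617. For 8-M-PDOT against vehicle (8171 and 7545), normexp with quantile normalization gave 5110 and 4892, and normexp with the 75th percentile 4973 lower. The 1.5-fold threshold gave 12807 and 13027, the 4-fold threshold 3345 and 2085, and bright probes 1387 and 2538. For 8-M-PDOT against melatonin (7327 and 6498), normexp with quantile normalization gave 4124 higher, and normexp with the 75th percentile 4576 and 4001. The 1.5-fold threshold gave 12466 and 11301, the 4-fold threshold 2665 and 1478, and bright probes 1302 and 1917. Probes past 2-fold with both compounds (1507 and 1536) were 656 and 783 after normexp with quantile normalization, 696 and 949 after normexp with the 75th percentile, and 2504 higher without a filter. The correlation (0.44) was 0.49 after normexp with the 75th percentile and 0.49 over probes well above background on all arrays. The thresholds and the bright-probe counts change by construction, and the cause of the other moves was not tested.

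For 8-M-PDOT against vehicle, the share of higher among 2-fold probes (52.0%) was 43.5% with median scaling (7027 and 9118), 47.4% with quantile normalization (7529 and 8359) and 59.2% with the 75th percentile over probes above background on all arrays (9385 and 6473), so which direction held more probes depended on the scaling, as it did for 8-M-PDOT against melatonin (46.2% with median scaling and 57.1% with the last of these). The median log2 ratio of all probes for 8-M-PDOT against vehicle shifted by 0.17 with normexp and the 75th percentile, by -0.11 with quantile normalization, by -0.14 with median scaling and by 0.12 with the 75th percentile over probes above background on all arrays. The housekeeping list median for melatonin (0.12) was 0.22 after normexp with quantile normalization, 0.21 after quantile normalization, 0.18 with the 75th percentile over probes above background on all arrays, and 0.22 in the deposited table. For 8-M-PDOT against vehicle (0.07) it was -0.31, -0.33, 0.20 and -0.31 in that order, and -0.07 with median scaling. For 8-M-PDOT against melatonin (0.17) it was -0.37, -0.39, 0.23 and -0.39, with 0.060 for median scaling and 0.10 for normexp with the 75th percentile.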

Other observations

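Probes of the name series ASMM10UP, whose meaning the files do not state, had more high than low probes with melatonin. Of 493 well above background on at least 1 of the 3 arrays, 53 were at least 2-fold higher on the melatonin array than on the vehicle array and 13 lower, where random lists of like brightness gave medians of 27 (18 to 37 over the central 95% of lists) and 22 (14 to 31). On the 8-M-PDOT array 82 were higher and 73 lower, where random lists gave 83 (67 to 99) and 59 (46 to 73). Between the compounds, 69 were higher and 90 lower on the 8-M-PDOT array, where random lists gave 77 (62 to 93) and 52 (40 to 65). The list medians were at percentiles 87.9, 11.4 and 0 of the random lists in these 3 comparisons. They include members dim on both arrays compared, which entered at or near the floors. Of the 493, 457, 459 and 480 were measured, with medians of -0.018, -0.105 and -0.062, against -0.066, 0.005 and -0.041 over all 493. The sign for 8-M-PDOT against vehicle differed between the 2, so nothing is drawn from the percentiles. Of 21 list medians set against random lists, 9 lay outside the central 95% of random lists, where 5% would by chance, though the lists overlap and share arrays. Members at the floors also set some of these medians. For 8-M-PDOT against vehicle the median of the lincRNA-named probes and the upper bound of its random lists were both 0.1244, the gap between the floors. The count of 9 is therefore no measure of how many lists changed.

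Taking each array in turn as the reference gave covariances of the other arrays' log2 ratios of 0.40 with vehicle, 0.05 with melatonin and 1.45 with 8-M-PDOT, over 48681 probes. The correlations across probes were 0.44, 0.06 and 0.87. If the deviations of single arrays are unrelated, these covariances are the variance particular to each array. Under that condition the 8-M-PDOT array stands furthest apart, and the vehicle array carries more of the melatonin-against-vehicle spread than the melatonin array does. A response shared by both compounds would break the condition and would also raise the covariance with vehicle as the reference. The values cannot tell these apart, which limits what the melatonin counts and the probes shared by both compounds show.

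The tests of explanations below were all chosen after the results were seen. Noise of dim probes behind the larger number of differing probes on the 8-M-PDOT array would spare bright ones, yet 40.2% of probes with a mean log2 signal of at least 10 differed 2-fold from vehicle on the 8-M-PDOT array, against 9.97% on the melatonin array. A trend of the ratio with brightness would be removed by quantile normalization, which left 15888 probes, 3.22 times the melatonin count. A local artefact would leave blocks on the array, and blocks held 0.469% of the variance of the ratio, where 0.276% arises by chance and the melatonin ratio had 1.18%. The signals of the treated arrays had already been detrended, which could remove a smooth artefact beforehand. The block shares therefore cover only what detrending left. An effect of 8-M-PDOT may underlie the difference as a hypothesis, but a difference between the cultures, their cell mix or the RNA preparations stays open. So do the solvent, which the labels give for the vehicle alone, and the position on the slide, because each condition has 1 array.

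The second pattern was among the 230 probes at least 64-fold higher on the 8-M-PDOT than on the vehicle array. Of these, 176 were also higher on the melatonin array than on the vehicle array (76.5%, median log2 ratio 0.67), against 46.3% of 32054 other probes as dim on the vehicle array. Low readings of the shared vehicle array could produce this, but 189 probes chosen against the melatonin array instead, with no use of the vehicle array, had a median of 0.43, with 119 of them higher (63%) against 47% of 25323 other probes as dim, a smaller gap, so low readings may still account for a part. A constant small share of the same RNA in the melatonin sample would give a similar share for every probe, and over 44 probes where such a share would at least double the vehicle level the ratio of its upper to its lower quartile was 3.03, between limits of 1.5 and 5 set after the values were seen, so this stays open (how far noise widens the ratio was not tested). A weaker response to melatonin of the same transcripts is a further hypothesis that was not tested. The spike-in control probe E1A_r60_a107, which is not among the study probes, had the same pattern. Its log2 ratio against vehicle was 8.05 on the 8-M-PDOT array and 1.22 on the melatonin array, and this single probe decides nothing.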
